A study of Mus musculus with 8 samples.

How the data were processed

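Epididymal white adipose tissue, the gonadal fat depot of male mice, was sequenced from 4 wild type (WT) and 4 Ccdc92 knockout (KO) samples on a C57BL/6 background, with 1 RNA library per sample. The WT animals were littermates of matching age, and all animals received a diet with 60% of calories from fat, 20% from protein and 20% from carbohydrate for 14 weeks, per the labels' protocols. Group and replicate number came from the sample labels, and all 8 columns of values carried the name of 1 sample. No label states that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

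The deposited signal was a normalized count per gene. STAR 2.7.7, DESeq2 and the build GRCm38.p6 are named per the submitters' processing notes, without the role of each. The read counter, its strand setting, its treatment of reads shared between genes, the annotation and any filter are not given in the sources used here. Values of closely related gene copies (Hba-a1 and its twin, the Defb genes, Ly6f, Orm3) and of overlapping genes are therefore uncertain to the extent that reads were split or shared between them. Within a library, 100.0% of the deposited values above 0 were whole multiples of 1 step, with a tolerance of 0.01 of a read. Dividing by that step gave whole reads, and the implied factor of each library (0.8246 to 1.1702) equalled the median-of-ratios factor recomputed from these reads to the printed digits. The table held 24821 genes, and the smallest sum of reads over the 8 libraries was 10, reached by 361 genes. Of the gene identifiers, 24558 matched GENCODE M21, an annotation of GRCm38, with their version and 24802 without it, and 19 did not match. Coordinates come from that annotation.

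Recovered reads per library ran from 23681088 to 33817478. Intervals and floors given for read counts are exact Poisson at 95% and cover counting error only. A fold against a group with no read was computed against a floor of 3 reads over the group.

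All gene-level results came from limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a design of group alone, a variance trend and robust moderation. Genes with a normalized count of at least 10 in at least 4 of the 8 libraries entered, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are KO over WT on the log2(normalized count + 1) scale, which understates changes of low genes. Normalized values are not counts, so the count models edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, run on the recovered reads, served as alternatives. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 38 lists. Each list was also tested with an estimated correlation, with fry and with an exact permutation of its mean log2 value per library.

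The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Ccdc92, the 12 largest rises and the 12 largest falls among genes past the test with a mean of at least 50 and no overlap between groups (predicted genes and pseudogenes left out), up to 4 members per list with the smallest p as examples, and 20 genes of interest. Here 1 to 3 of those examples are printed for most lists, and which ones was decided after their values, and how many of them changed sign with a covariate, had been seen. Counts over all 159 called genes of the rule, printed or not, are therefore given with the alternatives. Some list members are counted in their lists and not reported by name here. The lists covered adipocytes, macrophages (general, lipid-associated and resident-type), dendritic, T, B and NK cells, neutrophils, mast cells, fibroblasts with adipocyte progenitors, endothelium, mural cells, mesothelium, epididymis, skeletal muscle, red cells and Schwann cells. Further lists covered cytokines, inflammasome, interferon, MHC class II, lysosome, extracellular matrix, lipogenesis, lipolysis, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle with branched-chain amino acid catabolism, thermogenesis, insulin signalling, cholesterol synthesis, cell cycle, cilium, ER stress, hypoxia, immediate early genes and neighbours of Ccdc92.

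The fit was tested on simulated counts of 18144 genes for KO against WT. It called 6.1% of the genes changed by 1.5-fold in the right direction, 44% at 2-fold, 81.6% at 4-fold and 92% at 8-fold, and 9 of 17897 unchanged genes. Of the 38 lists, it called the 2 that carried simulated changes and 0 others. The simulated genes were drawn independently of each other, and only a small part of them was changed, so these rates hold for that setting alone. They do not give the rate of false list calls where genes of a list vary together, as in the data (estimated correlation 0.84 for the cell cycle list). Libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 27 to 453.7 over the pairs, so no pair agreed within sampling noise. This does not exclude separate libraries made from the same tissue or animal. Alternatives were the 2 count models, TMM factors, quantile normalization, pseudocounts of 0.5 and 8, no filter, a minimum of 50, moderation without the robust option, library weights, the macrophage or adipocyte list mean as a covariate, a replicate block and each library left out. After the data were seen, leaving out WT replicate 4 and KO replicate 3 together, and the mean of Crisp1 and Defb42 as a covariate, were added.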

Results

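Messenger RNA of epididymal white adipose tissue was measured in 4 WT and 4 Ccdc92 KO libraries after 14 weeks of high-fat feeding, to ask how loss of Ccdc92 alters gene expression in this depot. Ccdc92 encodes a coiled-coil protein, and human variants near it are associated with fat distribution and insulin resistance. Reads assigned to genes came to 29887921, 27760429, 28845333 and 28524000 in WT replicates 1 to 4 and to 24488534, 33739252, 33817478 and 23681088 in KO replicates 1 to 4. The first principal component held 60.2% of the variance and set the groups apart, with WT from -88.9 to -41.5 and KO from 49.4 to 106.3. Correlations of log2 values across genes, which are not independent replicates, were 0.94 to 0.972 between WT libraries, 0.952 to 0.983 between KO libraries and 0.854 to 0.933 between groups.

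The targeted gene Ccdc92 (ENSMUSG00000037979.13, chromosome 5, 124834418 to 124862424, minus strand, GRCm38) was lower in all 4 KO libraries. Its reads numbered 59, 71, 114 and 106 in WT and 8, 6, 9 and 4 in KO, with 95% exact Poisson intervals of 44.9 to 76.1 for the lowest WT library and 4.12 to 17.1 for the highest KO library. Normalized counts were 81.9 ± 24.7 (SD, n = 4) in WT and 7.21 ± 2.58 (SD, n = 4) in KO, so that KO retained 8.81% of the WT mean. The log2 fold change was -3.34 (SE 0.33, limma adjusted p = 0.000383), and a two-sided exact permutation test over 70 splits gave p = 0.0286, the smallest it can give. The labels used here do not say which part of the gene was deleted.

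In KO fat, genes of mature adipocytes, lipid handling and mitochondrial metabolism were higher, and genes of macrophages, mast cells, lysosomes and dividing cells were lower. These lists passed camera at its preset correlation. With an estimated correlation 0 of the 38 lists passed (0 at an unadjusted p under 0.05, smallest adjusted p = 0.483). The value 0.483, printed for many lists below, is tied by the adjustment, over unadjusted camera p values from 0.0807 (adipocyte) to 0.216 (endothelial). By fry 24 lists passed, but fry asks whether a list changes at all, not whether it changes more than other genes. Adrb3, the beta-3 adrenergic receptor of adipocytes, was 22.8-fold higher in KO on the fitted scale. Trem2, a lipid-sensing receptor of macrophages, was 17.6-fold lower. Crisp1, an epididymal secretory protein, had normalized counts of 26574.7 to 71824.5 in WT and 0 to 37.6 in KO, while the epididymis list fell in 2 of 6 measured members and did not pass (camera adjusted p = 0.068, and adjusted p = 0.483 with an estimated correlation). Other tract transcripts went the opposite way in a single library, such as Lcn8, an epididymal lipocalin, at 107.5 in KO replicate 3 and 0 to 1.9 in WT. Of 17798 genes tested, 7423 (41.7%) passed limma's test at an adjusted p under 0.05, 3592 higher and 3831 lower in KO. A change of at least 2-fold was fitted for 1145 of the higher and 1924 of the lower genes, and of at least 16-fold for 6 and 155. The groups did not overlap in 7496 genes (42.1%), where chance gives 2.86%. Without WT replicate 4 and KO replicate 3, 5943 genes passed, 2740 higher and 3203 lower. Quantile normalization turned the split to 4593 higher and 3257 lower and moved the median log2 fold change of all genes by 0.104. With the macrophage list mean, the adipocyte list mean or the mean of Crisp1 and Defb42 as a covariate, limma called 0 genes, with 1068, 1085 and 2673 at an unadjusted p under 0.05. These covariates lay 90%, 92.8% and 94.4% between the groups.

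**Figure D1:**
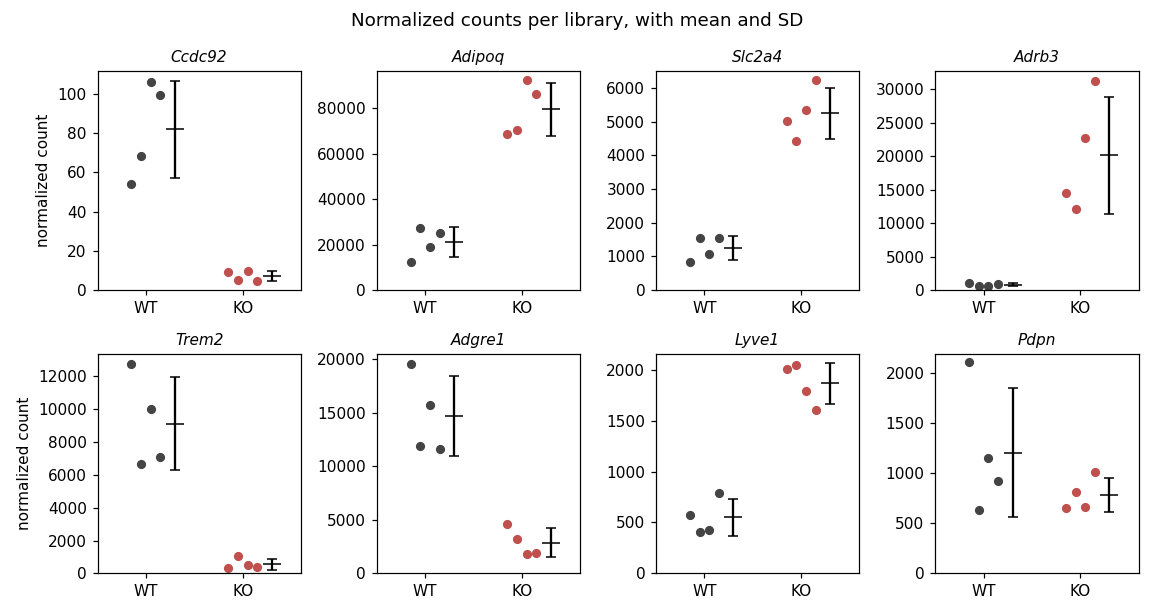
Normalized counts (y axis, from 0) of 8 genes in the 4 WT and 4 KO libraries, each point a library, with the mean and SD beside them. The groups did not overlap for any of these genes except Pdpn, whose counts were 1204 ± 641 in WT and 784 ± 167 in KO (SD, n = 4).

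The largest rises were in Orm3, an acute phase glycoprotein, at a log2 fold change of 5.05 (SE 0.34), Cyp2e1 at 4.53 (SE 0.61), Adrb3 at 4.51 (SE 0.30) and Cfd, the adipokine adipsin, at 4.38 (SE 0.47). Tmem88b (3.45), Pck1 (3.36), Adgrg2 (3.31), Fam13a (3.26), Retn (3.24), Mycl (3.22), Smyd1 (3.19) and Mogat1 (3.05) completed the 12, all with limma adjusted p values of 0.00256 or less. Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase that supplies glycerol for triglycerides in fat, and Retn encodes resistin. Adipocyte markers rose in 18 of 20 members, also 18 when adjusted over the list alone, with a median log2 fold change of 1.70 (camera adjusted p = 5.53e-09, and adjusted p = 0.483 with an estimated correlation). Adiponectin (Adipoq) rose from 20990 ± 6608 to 79420 ± 11790 (SD, n = 4), a log2 fold change of 1.97. Car3 rose by 2.56, the insulin-regulated glucose transporter Slc2a4 by 2.12 and the adipocyte regulator Pparg by 1.00. The 2 members that did not pass were Cd36 (0.02), named after its value was seen, and leptin, Lep (-0.23, limma adjusted p = 0.75). Lep ranged from 23157.7 to 63660.8 in WT and from 15451.6 to 80833.1 in KO. Across these libraries Crisp1 moved in the opposite direction to the adipocyte list, at 26574.7 or more in every WT library and at most 37.6 in KO. Since Crisp1 set all WT libraries apart from all KO libraries, it must go with or against every list that does so. Its direction, here and in the paragraphs below, can therefore neither show nor exclude a link between tract tissue and a list.

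Lipid and energy metabolism genes rose together. Genes of lipolysis and lipid storage rose in 16 of 20 members, 17 when adjusted over the list alone (camera adjusted p = 7.12e-08, and adjusted p = 0.483 with an estimated correlation), among them hormone-sensitive lipase Lipe (1.81) and Lpin1 (1.57). De novo lipogenesis genes rose in 11 of 16 members, likewise 11 when adjusted over the list alone (camera adjusted p = 0.000255, and adjusted p = 0.483 with an estimated correlation). Thrsp (2.47), the stearoyl-CoA desaturase Scd1 (2.37) and fatty acid synthase Fasn (1.29) were among them, and Scd1 lost its call under quantile normalization (0.77, limma adjusted p = 0.231). Fatty acid oxidation genes rose in 17 of 21 and fell in 1, against 17 and 2 when adjusted over the list alone (camera adjusted p = 0.000121, and adjusted p = 0.483 with an estimated correlation). Eci1 rose by 1.29 and Etfa by 0.87, while the member that fell was Cpt1a (-0.67), named after its value was seen, which missed the threshold without WT replicate 4 and KO replicate 3 together (limma adjusted p = 0.0535). Oxidative phosphorylation genes rose in 26 of 30 members, and in 26 when adjusted over the list alone, with a median of 0.52 (camera adjusted p = 8.96e-09, and adjusted p = 0.483 with an estimated correlation). Ndufv1 (0.77) and Cox8a (0.79) were examples. Genes of the tricarboxylic acid cycle and branched-chain amino acid catabolism rose in 23 of 24 members, again 23 when adjusted over the list alone (camera adjusted p = 2.99e-10, and adjusted p = 0.483 with an estimated correlation). Pcca (1.11) and Dbt (1.35), both of branched-chain catabolism, were among them. The share of reads from the mitochondrial genome was 2.73% to 3.63% in WT and 3.75% to 4.38% in KO. Insulin signalling genes rose in 11 of 20 and fell in 4, the same counts when adjusted over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.483 with an estimated correlation). The insulin receptor Insr rose by 0.78 and Irs1 by 1.12. That list lost its call under quantile normalization (camera adjusted p = 0.0921). The male tract gene Crisp1 was lower in every KO library than in any WT library, opposite to all of these groups.

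Macrophage genes fell. General macrophage markers fell in 18 of 20 members, 19 when adjusted over the list alone, with a median of -1.88 (camera adjusted p = 2.64e-09, and adjusted p = 0.483 with an estimated correlation). Adgre1, the F4/80 antigen, fell from 14710 ± 3752 to 2887 ± 1320 (SD, n = 4), Cd68 had a log2 fold change of -2.73 and the complement gene C1qc one of -1.36. Markers of lipid-associated macrophages, which surround dying adipocytes in obese fat, fell in 18 of 19 members and rose in 1, unchanged when adjusted over the list alone, with a median of -3.13 (camera adjusted p = 2.07e-08, and adjusted p = 0.483 with an estimated correlation). Trem2 fell from 9125 ± 2828 to 564.7 ± 340.2 (SD, n = 4), Atp6v0d2 had a log2 fold change of -4.25 and Itgax, which encodes CD11c, one of -3.70. Acp5 was the member that rose (0.95), named after its value was seen. Resident-type macrophage markers went both ways, 6 of 12 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.511). Lyve1 rose from 549.1 ± 177.7 to 1865 ± 204.2 (SD, n = 4) and Cd163 by 1.45, while the mannose receptor Mrc1 was 2.01-fold lower. Lysosome genes fell in 18 of 20 members, and in 18 when adjusted over the list alone (camera adjusted p = 7.91e-09, and adjusted p = 0.483 with an estimated correlation), with Grn at -1.39. Crisp1 was higher in every WT library than in any KO library, in the same direction as these macrophage and lysosome genes, which its separation of the groups fixes. In WT replicates 1 to 4, Crisp1 had 37712, 74687, 68671 and 28382 reads and Trem2 had 13885, 6921, 10773 and 7588. Their order among the WT libraries differed, but 4 libraries are too few to weigh a link.

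**Figure D2:**
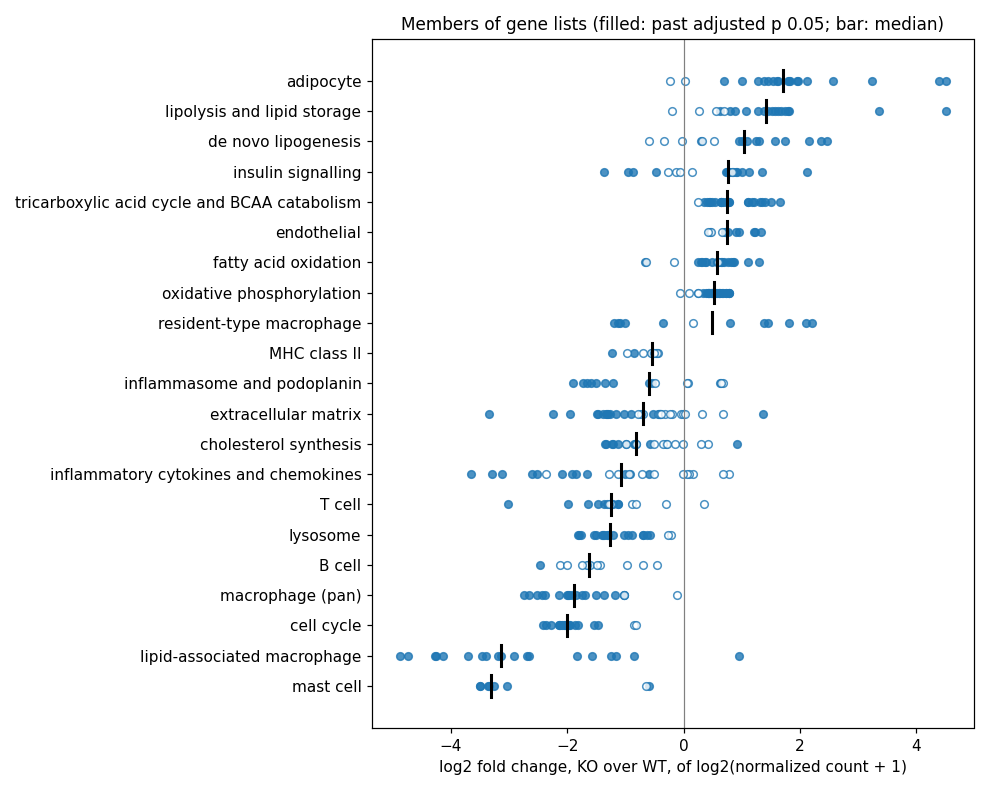
Log2 fold change of KO over WT (x axis) for each measured member of the 20 lists past camera's preset-correlation test and of the resident-type macrophage list, which did not pass. Filled points passed limma's test for that gene, and bars mark list medians, from -3.31 for mast cells to 1.70 for adipocytes.

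Mast cell genes fell in 7 of 8 members, and in 7 when adjusted over the list alone, with a median of -3.31 (camera adjusted p = 4.5e-05, and adjusted p = 0.483 with an estimated correlation). The mast cell proteases Mcpt4 (-3.35) and Cpa3 (-3.50) were examples. T cell genes fell in 10 of 16 members, 12 when adjusted over the list alone (camera adjusted p = 0.00139, and adjusted p = 0.574 with an estimated correlation), among them Il7r (-3.01) and Cd28 (-1.36). In the B cell list, 1 of 12 members fell, Cd22 (-2.47), and also 1 when adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.671 with an estimated correlation). The B cell call was lost without WT replicate 1 (0.0552), WT replicate 4 (0.0749), KO replicate 2 (0.0608) or KO replicate 4 (0.0566), each a camera adjusted p. Antigen presentation genes of MHC class II fell in 3 of 10 members, 2 when adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.574 with an estimated correlation), among them H2-DMb1 (-1.24) and its regulator Ciita (-0.86). Without WT replicate 4 this list had a camera adjusted p of 0.0636. Both the B cell and the MHC class II list also lost their calls in the DESeq2 fit (camera adjusted p = 0.0607 for each) and with library weights (0.0966 and 0.06). Crisp1 was higher in WT alongside these lists too, at 26574.7 or more.

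Cytokine and chemokine genes fell in 12 of 24 members, 13 when adjusted over the list alone (camera adjusted p = 0.00139, and adjusted p = 0.483 with an estimated correlation). Tnf (-3.11) and the chemokine Ccl3 (-3.28) were among them. Ccl2, a chemokine that recruits monocytes, fell by 1.91 (limma adjusted p = 0.0409), a call lost when any single WT library was left out, without KO replicate 1 (limma adjusted p = 0.0539), without KO replicate 3 (0.0877), without WT replicate 4 and KO replicate 3 together (0.11), and in edgeR's test (0.0664). With WT replicates 1 to 4 left out in turn, the limma adjusted p of Ccl2 was 0.104, 0.0626, 0.0767 and 0.0558. Il1b did not pass, at 26.7 ± 15.1 in WT and 44.4 ± 27.7 in KO (SD, n = 4). Inflammasome genes, listed with podoplanin, fell in 9 of 15 members and rose in 1, with the same counts when adjusted over the list alone (camera adjusted p = 0.0067, and adjusted p = 0.483 with an estimated correlation). Casp1 (-1.59) and P2rx7 (-1.22) fell, and the sensor Nlrp3 was 2.83-fold lower. The member that rose, named after its value was seen, was Txnip (0.63), a call lost under quantile normalization (limma adjusted p = 0.059) and without WT replicate 1 (0.0508), WT replicate 3 (0.0596), KO replicate 3 (0.056) or WT replicate 4 and KO replicate 3 together (0.0634). Podoplanin, Pdpn, had a log2 fold change of -0.50 that did not pass (SE 0.34, limma adjusted p = 0.263). WT replicate 1 held the highest Pdpn value, 2110.8, and the other WT libraries 628 to 1151.1. Crisp1 was again higher in every WT library than in any KO library.

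Genes of the extracellular matrix fell in 14 of 31 members and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.000957, and adjusted p = 0.574 with an estimated correlation). Collagen genes Col1a1 (-1.48) and Col6a3 (-1.33), the metalloprotease Mmp2 (-1.96) and Tgfb1 (-1.29) fell, and Thbs1, named after its value was seen, rose (1.36). Thbs1 lost its call without WT replicate 1 (limma adjusted p = 0.0593), WT replicate 3 (0.0596), KO replicate 3 (0.0539) or WT replicate 4 and KO replicate 3 together (0.0715). Col6a3 missed the threshold without WT replicate 4 and KO replicate 3 together (-1.07, limma adjusted p = 0.0518). Cell cycle genes fell in 18 of 20 members, 19 when adjusted over the list alone, with a median of -2.01 (camera adjusted p = 1.16e-07, and adjusted p = 0.483 with an estimated correlation), among them Cdk1 (-2.05) and Plk1 (-2.09). Cholesterol synthesis genes fell in 10 of 21 members and rose in 1, against 11 and 1 when adjusted over the list alone (camera adjusted p = 0.0067, and adjusted p = 0.574 with an estimated correlation). The regulator Srebf2 fell by 0.82, and Fdft1, named after its value was seen, rose (0.92). Endothelial genes rose in 8 of 12 members, 9 when adjusted over the list alone (camera adjusted p = 0.000255, and adjusted p = 0.483 with an estimated correlation), among them the vascular endothelial growth factor receptor Kdr (1.21) and Robo4 (1.32). Crisp1 went the same way as the matrix, cell cycle and cholesterol genes and the opposite way to the endothelial genes.

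The 12 largest falls included Crisp1, Serpina1f, Spink8, Serpina16, Defb28, Defb43 and Akr1b7, genes known from the epididymis or vas deferens, the ducts that carry sperm from the testis. Crisp1 had a log2 fold change of -12.91 (SE 0.96, limma adjusted p = 0.000182), Serpina1f one of -10.31, Spink8 -10.01, Serpina16 -9.16, Defb28 -8.91, Akr1b7 -8.89, Glb1l3 -8.46 and Ceacam10 -8.32. Against a floor of 3 KO reads, Ly6f, with 6172 reads in WT and none in KO, was at least 1830-fold lower (lower limit of a two-sided 95% counting interval 1480), and Defb43, with 2695 and none, at least 797-fold lower (648). Cwh43 had 7785 WT and 3 KO reads, a ratio of 2300 (95% counting interval 788 to 11200), and Atp10b had 4493 and 2, a ratio of 1990 (552 to 16500). The WT libraries differed in which tract genes they held. Akr1b7 was 80635.9 in WT replicate 4 and 188.1 to 211.6 in the other WT libraries, whereas Adam7 was 0.9 in WT replicate 4 and 7804.6 to 19828.7 in the others. The KO libraries differed as well, with Adam7 at 41.4, 272.6, 387 and 0 in KO replicates 1 to 4, the first 3 of them above WT replicate 4. The epididymis list had 6 of 13 members measured, of which 2 fell, Crisp1 and Defb42 (-6.56), and 3 when adjusted over the list alone (camera adjusted p = 0.068). Of the 7 members that did not enter the test, 6 were higher in KO replicate 3 than in every other library. They were Lcn8 (107.5), Rnase10 (69.9), Lcn9 (55.9), Lcn10 (36.5), Teddm1a (27.9) and Cst8 (20.4), with at most 1.9, 8.4, 0, 0, 0.9 and 8.7 in WT. The remaining one, Spinkl, was 5.6 to 150 in WT and 0 to 0.9 in KO, and all 7 were named after their values were seen. Without WT replicate 4 the epididymis list passed at the preset correlation (camera adjusted p = 0.028), as it did without KO replicate 3 (0.0189), without both (0.00226) and under quantile normalization (0.0359). With an estimated correlation and all 8 libraries its camera adjusted p was 0.483. Adam7 (-5.04, limma adjusted p = 0.232) passed without WT replicate 4 (-8.24, 0.0127) and without both libraries (0.0151), and with all 8 libraries in edgeR (-5.97, 0.0356), in DESeq2 (-6.00, 0.00843) and with library weights (0.0389). Rnase9, another member, also missed limma's test as reported. It passed without WT replicate 4 (-9.39, limma adjusted p = 0.00587), without KO replicate 3 (-8.89, 0.0232) and without both (-11.21, 0.000128). In edgeR it passed at -5.65 (adjusted p = 0.0376), and with library weights at -9.51 (limma adjusted p = 0.00361).

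**Figure D3:**
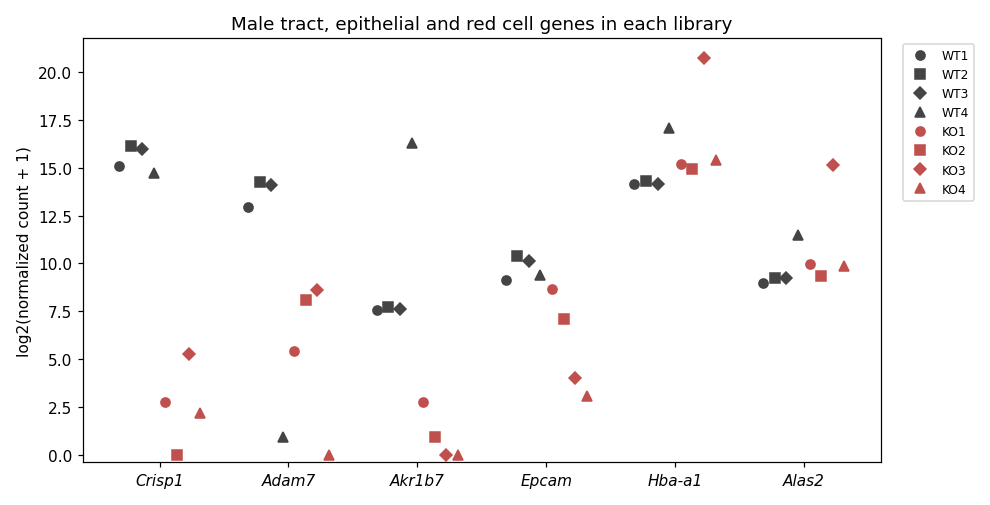
Log2(normalized count + 1) (y axis) of 6 genes in each library, gray for WT and red for KO, with the symbol marking the replicate number. Crisp1 was at 26574.7 or more in all WT libraries, Adam7 was low in WT replicate 4, and Hba-a1 reached 1761183.2 in KO replicate 3.

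Other lists did not pass camera's test at the preset correlation. Members that passed limma's test numbered 4 higher of 10 for dendritic cells, 1 lower of 10 for NK cells, 3 higher and 1 lower of 6 for neutrophils, 1 higher and 2 lower of 14 for fibroblasts and adipocyte progenitors, and 1 higher and 1 lower of 10 for mural cells. Among neutrophil genes S100a9 rose by 2.71, and Ltf, a secretory protein also of epithelia, fell by 7.29, with 141.4 in WT replicate 4 against 2545.6 to 3714.9 in the other WT libraries. Mesothelial markers had 2 lower of 10, among them the keratin Krt18 (-2.23). Schwann cell markers had 1 higher and 3 lower of 7, among them Ncam1 (-4.70), and skeletal muscle 1 higher and 1 lower of 7. Hemoglobin and red cell genes had 0 of 7 past limma's test, 0 at an unadjusted p under 0.05, 0 past edgeR's test and 2 past that of DESeq2. Without WT replicate 4 and KO replicate 3, the list passed as higher in KO at the preset correlation (camera adjusted p = 0.00226), with Hba-a1 at 0.98 (limma adjusted p = 0.00782). With all 8 libraries its estimated correlation was 0.95, and camera with that correlation gave an adjusted p of 0.798. Hemoglobin took 18% of the reads in KO replicate 3 and 1.75% in WT replicate 4, against 0.233% to 0.495% in the remaining libraries. Interferon genes had 3 higher and 2 lower of 20, cilium genes 6 and 3 of 31, ER stress genes 3 and 10 of 20, hypoxia genes 5 and 1 of 17, and immediate early genes 1 and 4 of 17. The ER stress list (camera adjusted p = 0.0602) passed as lower under quantile normalization (0.0193), without WT replicate 4 (0.0221) and without WT replicate 4 and KO replicate 3 (0.0212), and the NK cell list (0.398) passed as lower without KO replicate 3 (0.0468). With an estimated correlation and all 8 libraries, the camera adjusted p was 0.483 for ER stress and 0.824 for NK cells. Atf3, a stress-induced transcription factor on both the ER stress and immediate early lists, fell by 3.55, asparagine synthetase Asns was 2.82-fold higher and the angiogenic factor Vegfa rose by 2.48. The thermogenic list had 2 higher and 2 lower of 13, with the deiodinase Dio2 at -3.19, and Ucp1, at the minimum of 10 in fewer than 4 libraries and so not tested, was 32.1, 14.4, 4.6 and 233.1 in WT and 2.3, 5.1, 3.2 and 4.9 in KO. Median, mean and test did not all share a sign for the dendritic cell, neutrophil, skeletal muscle and thermogenic lists. The mesothelial list had a median of 0.46 and a test direction of lower, with a mean of 0 after rounding.

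Genes near Ccdc92 on chromosome 5 went both ways, 6 of 18 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.464). Aacs rose by 1.56 and Bri3bp fell by 1.49. Zfp664 rose by 0.29 (limma adjusted p = 0.0266), but lost the call without WT replicate 1 (0.0586), WT replicate 3 (0.0791), KO replicate 1 (0.0647), KO replicate 3 (0.0587), KO replicate 4 (0.0596) or WT replicate 4 with KO replicate 3 (0.0791), all limma adjusted p. Dnah10 did not pass in limma (1.34, adjusted p = 0.212), with 157.4, 56.4, 9.7 and 18.2 in KO against 6.4 to 21.5 in WT, and passed in DESeq2 (2.04, adjusted p = 0.0299) and with library weights (2.14, limma adjusted p = 0.0307).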

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

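All tests that weigh an explanation here were chosen after the results they concern were seen. Among 264 sets of 4 libraries compared for single values far from the rest, 25 stood out, where chance gives about 1 in 20. Some of the compared genes were named because of such values, so this count cannot be weighed against chance. Some values that stood out rest on few reads, such as 1 for Spinkl in KO replicate 2 and 2 for Atp10b in KO replicate 3.

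The split of the libraries by genotype gave 7423 genes, and 1 of the 35 possible splits into 4 and 4, the real one, gave as many. The highest count among the other splits was 0. Every other split mixes WT and KO libraries, so the difference between the groups itself widens their spread and lowers their counts. A rank of 1 among 35 is also the strongest outcome possible, so this comparison cannot exclude a chance division. For gene lists, 5 of the 35 splits gave at least the 20 lists of the real split, and the highest other split gave 22, so the number of lists past camera's preset-correlation test does not exclude chance.

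Tract transcripts stood apart between single libraries as well as between groups. In WT replicate 4, Akr1b7 was 80635.9 against 188.1 to 211.6 in the other WT libraries, while Serpina16 was 57.1 against 6607.5 to 12772.9, Defb28 15.9 against 1851.2 to 4179.4, Rnase9 2.8 against 1183.3 to 3353.4, Adam7 0.9 against 7804.6 to 19828.7 and Ltf 141.4 against 2545.6 to 3714.9. In KO replicate 3, Serpina1f was 86 and Rnase9 153.7 against 0 in the other KO libraries, Spink8 was 106.4 against 1.7 to 3.6 and Atp10b 2.1 against 0. Other tract genes were higher in KO replicate 3 than in every WT library: Lcn8 was 107.5 against 1.1 to 1.7 in the other KO libraries and 0 to 1.9 in WT, Lcn9 was 55.9 against 0 in all others, and Lcn10 was 36.5 against 0 to 0.9 in KO and 0 in WT. Rnase10 (69.9), Teddm1a (27.9) and Cst8 (20.4) were also highest there. Cst8 was at 0 in the other KO libraries. In KO replicate 2, Glb1l3 was 6 against 2.1 to 2.4 and Spinkl 0.9 against 0. Among genes of epithelia in general, Spint2 and Epcam lost their limma calls without WT replicate 3 (adjusted p = 0.0559 and 0.0528), without KO replicate 3 (0.0521 and 0.0579) and without WT replicate 4 and KO replicate 3 (0.0782 and 0.0842), and Epcam in edgeR (0.0579). Elf3 did not pass in limma (adjusted p = 0.0598), but did without KO replicate 1 (0.0203), without KO replicate 2 (0.046) and with a pseudocount of 8 (0.0393).

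Epididymis or vas deferens tissue carried along with the WT fat may account for the tract transcripts that were higher in WT. Such tissue would bring genes of epithelia in general, and a list of 17 such genes, none of them on the tract list, had a median log2 fold change of -4.06, with 16 lower in KO past limma's test. The most abundant of them, Spint2, Cldn3 and Cdh1, reached 2826.4, 1753.1 and 1553.1 in WT replicate 2, and 5 of the 17 were at 10 or more in all 4 KO libraries. Some of these genes and Crisp1 parted in KO replicate 1, where Crisp1 was 5.7 while Epcam was 406.8 against 569.7 to 1361.7 in WT, and Elf3 (193.1) and Spint2 (1175.6) lay above the lowest WT libraries (140.4 and 1063.2). Further genes were named after their values were seen. Krt5, a keratin, was 129.3 to 352.1 in WT and 0 in KO. Prm2, a protamine of sperm, was 574.2, 681.8, 1357.2 and 0 in WT and 0 to 75.2 in KO (limma adjusted p = 0.171). The smooth muscle gene Cnn1 was 7307 in WT replicate 4, against 178.9 to 241.4 in the other WT libraries. Myh11 was 25665.5 there, against 2038.3 to 3574.5. Cnn1 and Myh11 did not pass between groups (limma adjusted p = 0.314 and 0.72). An effect of genotype on tract genes cannot be told apart from the amount of tract tissue, since 94.4% of the variance of mean Crisp1 and Defb42 lay between the groups. A difference between the genotypes in how much tract tissue adheres to the fat also stays open and was not tested.

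The fall of macrophage genes with the rise of adipocyte genes was set against 3 technical or simple readings. A dilution of adipocyte RNA in WT by all other cells in equal measure would move other cell types alike. The endothelial minus the lipid-associated macrophage mean rose by 3.61 log2 from WT to KO (two-sided exact permutation p = 0.0286, the smallest possible). That difference follows from list changes already seen (mean log2 fold changes of 0.82 and -2.8). A dilution in unequal measure stays open, since adipocyte (1.83) and endothelial means were both higher in KO. An equal loss of macrophages of every kind would lower resident-type markers as much as lipid-associated ones. Their list means moved apart by 3.22 (exact permutation p = 0.0286). An unequal loss stays open, since 5 of the 12 resident-type markers were lower in KO and 6 higher. Macrophages brought with tract tissue stay open: with the mean of Crisp1 and Defb42 as a covariate, the log2 fold change of Trem2 went from -4.14 (SE 0.39) to -4.10 (SE 1.75), and the call ended (limma adjusted p = 0.332) because the standard error rose with a covariate that follows the groups. An effect of the genotype on macrophage state or number remains a hypothesis, as it cannot be told apart from the tract tissue or from unequal dilution.

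Hemoglobin took 18.005% of reads in KO replicate 3 against 0.36% to 0.495% in the other KO libraries, and 1.749% in WT replicate 4 against 0.233% to 0.258%, with Hba-a1 at 1761183.2 and 139301.1 in these libraries. The 10 most abundant genes took 25.5% of reads in KO replicate 3, against 9.4% to 11.4%. More blood in that tissue piece is a candidate explanation, since red cell genes other than hemoglobin and platelet genes, in 2 lists, were higher there than in the other KO libraries by list medians of 3.64 and 4.67 on the log2 scale, in 8 of 8 and 9 of 9 genes, of which 3 and 1 are also on other lists. An effect of the genotype as the source of the level in KO replicate 3 is argued against by the highest of the 3 other KO libraries, which lay at 1.98 times the median WT library. A smaller difference between the groups stays open, since without WT replicate 4 and KO replicate 3 Hba-a1 was higher in KO by 0.98 (SE 0.16, limma adjusted p = 0.00782) and the red cell list passed at the preset correlation (camera adjusted p = 0.00226).

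Tmem88b was 38.5 in WT replicate 2 against 16.5 to 18.7 in the other WT libraries. Cox8a was 8331.5 in KO replicate 3 against 6180 to 6361.2, and Srebf2 was 1435 there against 1766.2 to 1822.7. The clock gene Nr1d1 was 1564 in WT replicate 1 against 2139.7 to 2171.3 in the other WT libraries.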

How the results depend on the processing

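The mean of Crisp1 and Defb42 as a covariate and the removal of WT replicate 4 with KO replicate 3 were chosen after the data were seen. Apart from the 3 covariates, the settings kept the number of genes within 1.5 times of 7423, up to 9767 with library weights and 5943 without those 2 libraries. When single libraries were left out, 5641 to 7079 genes, 2710 to 3410 higher, 2931 to 3669 lower and 19 to 22 lists passed. On the recovered reads edgeR called 7435 genes and DESeq2 8336, of which 7141 and 7373 were shared with limma, all in the same direction. Deviations of WT and KO libraries with the same replicate number, 1 to 4, correlated at -0.14, 0.05, -0.04 and 0.17. Only the libraries of number 4 correlated best with each other. These values show no clear pairing by replicate number but cannot exclude one. With a replicate block 6266 genes and 22 lists passed. Under the block Zfp664 (limma adjusted p = 0.0726) and Spint2 (0.0594) missed the threshold, and Adam7 (0.0179), Rnase9 (0.0277), Elf3 (0.0464) and the epididymis (camera adjusted p = 0.0187) and ER stress (0.0314) lists passed. Ccdc92 kept its call outside the covariate fits, at -3.52 to -3.19 with single libraries left out, with adjusted p values from 1.92e-14 in DESeq2 to 0.712 over all alternatives. Among lists, 20 passed as reported, 24 by fry, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by exact permutation (20 unadjusted), where the smallest adjusted p was 0.0543. The smallest permutation p possible is 0.0286, which stays under 0.05 after adjustment over 38 lists only if many lists reach it together. No list could therefore pass the permutation by the size of its own change, and the 0 does not speak against any list. Outside the covariates and the 3 other list tests, named genes lost a call in 35 and gained one in 22 cases, and lists in 10 and 11. Depth limits genes with few reads, such as Ccdc92 in KO at 4 to 9 reads.

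With a covariate, limma called 0 genes in each of the 3 fits, 0 higher and 0 lower, with 1068 (macrophage), 1085 (adipocyte) and 2673 (tract) genes at an unadjusted p under 0.05, and 9, 10 and 19 lists passed camera. The covariates lay 90%, 92.8% and 94.4% between the groups, which at an unchanged residual spread multiplies a standard error 3.16, 3.73 and 4.22 times. Ccdc92 went from -3.34 (SE 0.33) to -3.60 (SE 1.09, limma adjusted p = 0.712), -3.85 (SE 1.28, 0.706) and -1.54 (SE 1.30, 0.596). With the macrophage covariate the log2 fold changes with a sign opposite to the reported one were Pck1 (-0.31), Fam13a (-0.65), Mycl (-0.11), Tnf (1.91), Ccl2 (2.80), Irs1 (-0.67), Col1a1 (0.51), Col6a3 (0.90), Zfp664 (-0.20), Mrc1 (0.28), Robo4 (-0.067), Eci1 (-0.25), Etfa (-0.023), Ndufv1 (-0.094), Insr (-0.17), Asns (-0.086), Aacs (-0.19), Dio2 (0.45), Cpt1a (0.54), Txnip (-0.56), Thbs1 (-1.45), Fdft1 (-0.56), Nnat (-0.091), Arntl (0.72), Npas2 (0.79), Tef (-0.22), Cdh1 (0.43) and Epcam (1.69). Lists with the opposite direction, each with its camera adjusted p, were, higher, cytokines (0.337), extracellular matrix (0.00381), cholesterol synthesis (0.955) and cell cycle (0.00395), and, lower, endothelial (0.614), interferon response (0.00559), de novo lipogenesis (0.864), lipolysis and lipid storage (0.634), fatty acid oxidation (0.216), oxidative phosphorylation (0.623), tricarboxylic acid cycle (0.852) and insulin signalling (0.955). With the adipocyte covariate the genes were Pck1 (-0.36), Fam13a (-0.13), Mycl (-0.10), Tnf (1.40), Ccl2 (1.90), Adipoq (-0.37), Pparg (-0.26), Irs1 (-0.36), Col1a1 (0.27), Col6a3 (0.41), Fasn (-0.66), Zfp664 (-0.36), Acp5 (-0.072), Cd163 (-0.15), Mrc1 (0.46), Robo4 (-0.60), Kdr (-0.32), Lpin1 (-0.36), Lipe (-0.63), Eci1 (-0.44), Etfa (-0.29), Ndufv1 (-0.16), Cox8a (-0.16), Insr (-0.26), Asns (-0.026), Aacs (-0.22), Dio2 (0.63), Cpt1a (0.54), Txnip (-0.36), Thbs1 (-1.62), Fdft1 (-0.33), Nnat (-0.64), Arntl (0.18), Npas2 (1.36) and Tef (-0.032). Lists by camera adjusted p were, higher, general macrophage (0.183), lipid-associated macrophage (0.374), cytokines (0.621), inflammasome (0.237), lysosome (0.024), extracellular matrix (0.0423) and cell cycle (0.621), and, lower, adipocyte (0.33), endothelial (1.49e-05), interferon response (0.00129), de novo lipogenesis (0.102), lipolysis and lipid storage (0.000642), fatty acid oxidation (0.00202), oxidative phosphorylation (0.237), tricarboxylic acid cycle (0.313) and insulin signalling (0.621). With the tract covariate the genes were Serpina1f (5.99), Spink8 (2.37), Ceacam10 (0.62) and Defb42 (3.72), and the lists, higher by camera adjusted p, T cell (0.0287), B cell (0.0694) and NK cell (0.000288). Among all 7423 called genes the sign turned in 2701 (36.4%), 3448 (46.5%) and 437 (5.9%) with the macrophage, adipocyte and tract covariates. Among the 159 called genes that the naming rule gave, it turned in 38, 52 and 7, of which 20, 26 and 3 are among the 73 not named here. None of the named genes passed limma's test in those fits. Group coefficients of the genes that make up a covariate average 0 in its fit, so these genes cannot all keep 1 sign. That covers Defb42 with the tract covariate, and Adipoq, Pparg, Lipe and the adipocyte list with the adipocyte covariate, whose turns therefore carry no information. For the other genes and lists, the cause of the turns was not tested beyond the overlap of covariate and group.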

Other observations

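The lists and genes in this part were chosen after the data were seen, and their tests with them. Adjusted p values of camera in this part cover only the lists added after the data were seen, fewer than the 38 of the main test. They are therefore not comparable with those of the main lists. Crisp1, at 26574.7 or more in WT and at most 37.6 in KO, and the adipocyte list, with a median log2 fold change of 1.70, differed between the same groups. Of the 13 messenger RNAs encoded by the mitochondrial genome, 11 were higher in KO past limma's test and 2 did not pass, with a median log2 fold change of 0.61 (camera adjusted p = 0.000245, and adjusted p = 0.466 with an estimated correlation). The median was 0.63 with TMM factors and 0.49 with quantile normalization. Peroxisome genes were higher in 16 of 21 members and lower in 1, with a median of 0.64 (camera adjusted p = 9.28e-06, and adjusted p = 0.466 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 20 of 80 members and higher in 0, with a median of -0.24 (camera adjusted p = 9.28e-06, and adjusted p = 0.619 with an estimated correlation). Among 17 circadian clock genes, 6 were higher, 2 lower and 9 did not pass (camera adjusted p = 0.0485, and adjusted p = 0.466 with an estimated correlation). Over all tested genes, 41.7% passed. Arntl (-1.50) and Npas2 (-2.43), which encode activators of the clock, were lower in all 4 KO libraries. Nr1d1 (1.57), Ciart (1.20) and Tef (0.68) were higher in all 4. Clock (-0.04), Per1 (0.32), Per2 (0.48) and Cry1 (0.33) did not pass (limma adjusted p = 0.822, 0.195, 0.0883 and 0.136). The labels give no time of collection.

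Retnla rose from 1089 ± 468 to 7102 ± 2112 (SD, n = 4), a log2 fold change of 2.76, angiotensinogen (Agt) by 2.86 and Nnat by 2.74. Of other genes examined beside them, Angptl8 (0.07), Fgf21 (-0.49) and Mest (-0.09) did not pass (limma adjusted p = 0.839, 0.484 and 0.934). The lactate receptor gene Hcar1 rose from 986 ± 225 to 4014 ± 1298 (SD, n = 4). Genes that fell in all 4 KO libraries included Gldc, of glycine breakdown, at -4.69, and the leukocyte surface genes Cd72 (-3.87), Clec12a (-2.84) and Cd83 (-1.85, SE 0.09). Cd83 was at 1460 ± 48.7 in WT and 405.7 ± 49 in KO (SD, n = 4).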
